A study of Mus musculus with 12 samples.

How the data were processed

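The study profiled polyadenylated RNA and small RNA of cardiomyocytes and nonmyocytes from 3 mouse hearts, with 3 libraries per fraction and assay, sequenced on an Illumina HiSeq instrument. Per the labels, polyadenylated RNA was bound to oligo(dT), fragmented chemically and made into single-end libraries that do not keep the strand. Small RNA libraries were made with the TruSeq small RNA kit, also per the labels. The deposited tables hold whole-number counts per gene and per mature microRNA arm, which the authors did not normalise. Bowtie, TopHat 1.3.0, HTSeq, DESeq and edgeR are named in the submitters' processing notes, without their roles, along with the mouse genome build mm9 (NCBIM37). Counting rules and read filters are not given in the sources used here.

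Polyadenylated RNA counts were deposited for 57683 genes of an annotation that joins 20692 Ensembl genes with lncRNA genes of the NONCODE catalogue. A gene's class and mm9 position were taken from that annotation. A total of 37111 genes were lncRNA by that annotation, and most of these carry only a catalogue number with no name beside it. Small RNA counts were deposited for 850 arms of 517 precursors, 68 of them on the strand opposite to the annotated precursor. The line with the library total was left out after it was checked to equal the sum of the others in all 6 libraries. Precursors named by a genomic clone numbered 134, of which 73 were given a microRNA name through the transcript identifier. The rest are named by position.

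How the counting treated reads in bases shared by several genes is not stated, and this can change a level. Some mitochondrial genes and some well-known lncRNA genes that overlap others stand at 0 in every library, while other overlapped genes hold counts. The share of a gene's exon bases that lie in other annotated genes was therefore computed, and genes with a large share are called uncertain beside their values. Members of near-identical families (globins, ribosomal proteins, let-7 and miR-133a copies) are uncertain too, since reads can fall on another copy.

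Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes with low counts were removed with filterByExpr (minimum count 10), and libraries were scaled with the trimmed mean of M values (TMM). The fractions were compared with edgeR's robust quasi-likelihood test, two-sided, and a Benjamini-Hochberg adjusted p under 0.05 was called. CPM values are computed from the deposited counts with TMM-scaled library sizes. The biological coefficient of variation was 0.251 in polyadenylated RNA and 0.639 in small RNA. Lists with at least 3 tested members were tested with camera (limma, preset correlation 0.01), and again with an estimated correlation and with fry. With an estimated correlation camera uses the few residual degrees of freedom of these libraries, which lowers power. A call lost there alone does not show that a list is unchanged. Of 26 gene lists 25 could be tested so, and of 12 microRNA lists 11. Same-direction shares of microRNAs and their host genes were tested by reassigning hosts 100000 times, one-sided.

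The samples' groups, the tests, the lists, the host pairs, the rule for named genes and all but 2 kinds of alternative were fixed before the data were examined. The rule names, in polyadenylated RNA and per direction, the 8 called genes with the largest fold at 20 CPM or more in every library of the higher group and the 8 with the highest mean, without overlap between groups. For 3 libraries against 3, chance gives no overlap for 10% of genes. For lncRNA genes the rule names the 5 highest and the 3 with the largest fold, and in small RNA the 8 highest and the 5 with the largest fold. The folds are taken at 5 and 100 CPM or more in every library of the higher group. Per list it names the 3 most abundant members and those with the largest fold each way. Members outside that rule, named where 5 or fewer went against their list or as further examples, and the 3p arm of miR-208a were chosen after their values were seen.

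Alternatives were other scalings (DESeq2's size factors, upper quartiles, library totals), no filter on low counts, DESeq2 1.42.0, limma voom, a test against a 2-fold change and the replicate number as a block. Each library was left out in turn, which also lowers power, so a lost call alone does not show that a fold depends on that library, as were mitochondrial genes and the 3 most abundant microRNAs. Chosen after the data were seen were leaving out lncRNA genes near coding genes and leaving out opposite-strand small RNAs.

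Nothing in the labels ties a library number to a heart, so p-values of single genes measure the spread between these libraries, which may be partly technical. With the preset correlation camera compares the members of a list with the other genes. Its p-values then rest on the spread between genes and do not measure that between libraries. Folds against a group with 0 counts are lower bounds set by 3 counts over the whole group, in which deeper libraries weigh more, and ratios with 1 to 3 counts divide summed counts by summed library sizes and carry exact 95% intervals. Both cover counting error only, since reads without molecular identifiers are not independent molecules. On simulated counts with the depth of the polyadenylated RNA libraries (14795 genes tested), the test recovered 49% of genes changed by 1 on the log2 scale and 100% of genes changed by 3, with 5 false calls among 14595 unchanged genes. On simulated small RNA counts (338 tested) it recovered 10% and 90%, with 3 false calls among 278. The simulated dispersion was 0.4 in small RNA and 0.06 in polyadenylated RNA, so depth and spread are not separated. In both simulations the changed list was called and 0 of 20 unchanged lists were, and 1% of 200 simulated host assignments passed the threshold. Simulated genes were drawn independently and the unchanged lists at random, so these runs do not test lists of correlated genes. Fewer simulated genes changed than were called in the data, as many up as down, so the scaling was not tested either. A few single genes that the rule names or that belong to a list are not reported here. No coordinates of another genome build and no genome sequence were used here.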

Results

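Hearts of 3 female FVB/NJ mice, an inbred laboratory strain, were dissociated at 12 weeks of age with collagenase perfused through the coronary vessels. Cardiomyocytes, the contracting muscle cells, were parted from the smaller nonmyocytes by gravity. Cardiomyocyte RNA was taken at once. Nonmyocytes were first grown in dishes into a culture described as mainly fibroblasts, the cells that make connective tissue. The labels differ on that culture, since the protocol speaks of 2 passages and the cell type label of a P1 culture. Each fraction gave 3 libraries of polyadenylated RNA, which hold messenger RNA and long noncoding RNA (lncRNA), and 3 libraries of small RNA, which hold microRNAs. Levels are CPM, counts scaled to the size of each library, given as mean ± SD over 3 libraries (n = 3) with cardiomyocytes first. Every log2 fold change is cardiomyocyte minus nonmyocyte, with its standard error after the ± sign.

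Total counts of polyadenylated RNA were 5956831, 26851830 and 26195634 in cardiomyocyte libraries 1 to 3 and 10792544, 8126422 and 10243774 in nonmyocyte libraries 1 to 3. Small RNA totals were lower and less even, with 412739, 3062706 and 6311625 in cardiomyocytes and 1255622, 549924 and 83170 in nonmyocytes. A floor of 3 counts equals 0.928 CPM in the deepest small RNA library and 20.4 CPM in the shallowest. Across genes, which are not independent replicates, log CPM of polyadenylated RNA correlated at 0.936 to 0.986 within a fraction and at 0.56 to 0.624 between fractions. In small RNA these ranges were 0.872 to 0.987 and 0.521 to 0.651. Mitochondrially encoded genes took 3.06%, 6.12% and 5.85% of the cardiomyocyte counts and 0.321%, 0.405% and 0.236% of the nonmyocyte counts.

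The polyadenylated RNA was compared to ask which messenger RNAs set cardiomyocytes apart from nonmyocytes of the same hearts. Genes of the contractile apparatus, of calcium handling and of mitochondrial energy metabolism rose in cardiomyocytes, and genes of the extracellular matrix and of cell division fell. With an estimated correlation, which also lowers power, calcium handling was not called (limma camera adjusted p = 0.0527). The lists of energy metabolism were not called either, namely oxidative phosphorylation (limma camera adjusted p = 0.0767), mitochondrially encoded genes (0.234), the citric acid cycle (0.0758) and fatty acid oxidation (0.0527). Myh6, the alpha myosin heavy chain of the adult mouse heart on chromosome 14 (55560766 to 55585764), held 60011 ± 11101 against 411.1 ± 58.2 CPM. Its log2 fold change was 7.19 ± 0.20 (edgeR quasi-likelihood adjusted p = 1.87e-10). At the other end stood Fn1, which codes for the matrix protein fibronectin, on chromosome 1 (71632094 to 71699746). It held 231 ± 64.2 against 15102 ± 1613 CPM, a log2 fold change of -6.03 ± 0.22 (edgeR quasi-likelihood adjusted p = 7.52e-10). Of 14734 genes tested, 4657 were higher and 4732 lower in cardiomyocytes and 5345 were not called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold differences were called for 3852 and 3869 genes. Scaling by library totals alone moved the median log2 fold change by -0.68, and 30.9% of the called genes were then higher in cardiomyocytes, against 49.6% with the scaling used here. One fraction was cultured and the other was not, so cell type and culture cannot be told apart in any comparison here.

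Among the 8 most abundant transcripts higher in cardiomyocytes was that of the oxygen store myoglobin (Mb), with 36647 ± 3255 against 235 ± 34.7 CPM. The ventricular myosin light chain Myl2 held 21500.1 ± 4752 against 137.02 ± 22.95 CPM, and the giant spring protein titin (Ttn) 18929.9 ± 4666 against 138.1 ± 20.4 CPM. Troponin T (Tnnt2) held 16796 ± 2608 against 127.9 ± 22.1 CPM and cardiac actin (Actc1) 14032 ± 2932 against 103.2 ± 15.8 CPM. Log2 fold changes of these 5 genes ran from 7.04 for Tnnt2 to 7.29 for Myl2. The mitochondrial genes mt-Co1 and mt-Cytb, which code for respiratory chain subunits, held 17069 ± 5303 against 567 ± 98.5 CPM and 14732 ± 6854 against 459 ± 144.7 CPM. The steepest differences at 20 CPM or more in every cardiomyocyte library were those of the potassium channel gene Kcna7 and of Fam179a, each with only 3 counts over the nonmyocyte libraries. Their ratios were 359 (95% interval 123 to 1743) and 387 (95% interval 132.1 to 1879). The Z-disc protein gene Myot (8.09 ± 0.58) and the transcription factor gene Zbtb16 (8.05 ± 0.60) followed. Lrrc2 (7.96), Gpihbp1 (7.86), Yipf7 (7.84) and Hhatl (7.83) completed that set. Gpihbp1 is also on the list of endothelial markers used below. Hhatl and Lrrc2 are uncertain, since 92.99% and 60.1% of their exon bases also lie in other annotated genes.

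The most abundant transcripts higher in nonmyocytes coded for secreted and cytoskeletal proteins. Smooth muscle actin (Acta2) held 359.6 ± 42.8 against 6357 ± 745 CPM and fibulin 2 (Fbln2) 92.5 ± 21.1 against 6057 ± 692 CPM. Biglycan (Bgn) held 104 ± 13.2 against 5619 ± 901 CPM, with 48.5% of its exon bases shared with other annotated genes. Type I collagen (Col1a1) held 81.0 ± 17.4 against 5378 ± 558 CPM, cytoplasmic actin (Actb) 431.1 ± 86.5 against 5249 ± 227 CPM, thrombospondin 1 (Thbs1) 56.2 ± 15.9 against 5184 ± 1276 CPM and filamin A (Flna) 164 ± 57.3 against 4553 ± 206.3 CPM. Their log2 fold changes ran from -6.52 for Thbs1 to -3.60 for Actb. The largest falls at 20 CPM or more in every nonmyocyte library belonged to Tnfrsf11b, which codes for the decoy receptor osteoprotegerin (-7.42 ± 0.48), and to the chemokine gene Ccl20 (-7.35). The chromatin protein gene Hmga2 (-7.25), Steap1 (-7.13) and the collagen gene Col11a1 (-7.11) were next. The growth factor gene Ereg (-6.85), the collagen gene Col12a1 (-6.83) and Gpr176 (-6.80, 45.6% of exon bases shared) followed. The highest adjusted p among the genes of this paragraph was 2.24e-08, for Steap1 (edgeR quasi-likelihood).

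Sarcomere and Z-disc genes, the contractile machinery, rose in cardiomyocytes as a group. Of 35 tested, 34 were higher, with a median log2 fold change of 7.10 (limma camera adjusted p = 1.19e-49, and adjusted p = 0.0303 with an estimated correlation). The exception was the nebulin gene Neb, at 0.36 and not called. Xirp1, which codes for an actin-binding repeat protein, had the largest change of the list (7.61 ± 0.31). Summed over the list, expression was 239277 ± 24892 CPM in cardiomyocytes and 6454 ± 489 CPM in nonmyocytes. Of the latter, the stress-responsive gene Ankrd1 alone held 2085 ± 135.7 CPM. The 26 members at 1000 CPM or more in cardiomyocytes stood in nonmyocytes at a median of 0.677% of that level. Among all 180 genes at 1000 CPM or more in cardiomyocytes the lowest such share was 0.511%. Calcium handling and ion channel genes rose in 32 of 33 cases, at a median of 6.49 (limma camera adjusted p = 2.63e-33, and adjusted p = 0.0527 with an estimated correlation). The ryanodine receptor Ryr2, the calcium release channel of the sarcoplasmic reticulum, held 3871 ± 1001 against 26.1 ± 4.26 CPM. The calcium-binding protein Hrc held 4827 ± 725 against 32.0 ± 6.20 CPM, while Gjc1, at 0.68, was not called. All 9 tested genes of the natriuretic peptide and fetal program rose, at a median of 6.30 (limma camera adjusted p = 6.11e-11, and adjusted p = 0.0527 with an estimated correlation). Among them were Nppa (6.75), Nppb (7.20) and the slow myosin gene Myh7 (2943 ± 197 against 16.9 ± 1.57 CPM). Apart from Nppa and Nppb, every tested gene of this list also belongs to the sarcomere list or the calcium handling and ion channel list. Its result is therefore not separate from theirs.

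Energy metabolism rose with the contractile genes. All 55 tested members of a list of nuclear genes of oxidative phosphorylation were higher in cardiomyocytes, at a median of 3.37 (limma camera adjusted p = 8.76e-37, and adjusted p = 0.0767 with an estimated correlation). That list holds the muscle forms Cox6a2 and Cox8b and not their general forms, of which Cox6a1 was lower (-0.97) and Cox8a not called (-0.26). The ATP synthase subunit gene Atp5b held 6803 ± 523 against 855 ± 32.0 CPM, and the muscle form Cox6a2 of a cytochrome oxidase subunit 6511 ± 1414 against 43.0 ± 5.02 CPM. The 7 tested mitochondrially encoded genes rose at a median of 4.74 (limma camera adjusted p = 3.03e-05, and adjusted p = 0.234 with an estimated correlation). These levels are uncertain, since 4 of the 13 such genes in the table stood at 0 in all libraries and 98.3% to 100% of the bases of mt-Co1, mt-Cytb, mt-Nd1 and mt-Nd2 overlap other annotated genes. Of 28 fatty acid uptake and oxidation genes 27 rose, at a median of 4.14 (limma camera adjusted p = 6.66e-28, and adjusted p = 0.0527 with an estimated correlation). The fatty acid carrier Fabp3 held 3446 ± 599 against 25.6 ± 2.50 CPM and lipoprotein lipase (Lpl) 6782 ± 865 against 158 ± 23.6 CPM. Cpt1a, a carnitine acyltransferase gene also expressed in liver, was the one that fell (-1.95 ± 0.29). All 20 citric acid cycle genes rose, at a median of 3.56 (limma camera adjusted p = 2.74e-20, and adjusted p = 0.0758 with an estimated correlation), with the isocitrate dehydrogenase gene Idh2 at 2685 ± 201 against 46.9 ± 4.98 CPM. Glycolysis was mixed, with 14 of 22 genes higher at a list median of 1.08 (limma camera adjusted p = 3.71e-05, and adjusted p = 0.192 with an estimated correlation). Those that fell were Aldoc, Eno1 (-2.56), Pgam1 (-1.09), the lactate carrier gene Slc16a3 (-3.97) and the glucose carrier gene Slc2a1 (-0.92). Aldoc had 2 counts over the cardiomyocyte libraries, and its ratio toward nonmyocytes was 39.4 (95% interval 10.5 to 332). Ldha (0.36), Pgk1 (0.20) and Pkm2 (-0.06) were not called. The insulin-responsive glucose carrier Slc2a4 held 1819 ± 326.4 against 12.1 ± 1.21 CPM and aldolase A (Aldoa) 5888 ± 561 against 1909.6 ± 95.8 CPM.

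Matrix and fibroblast genes fell in cardiomyocytes. Of 62 extracellular matrix genes 55 were lower, at a median of -3.95 (limma camera adjusted p = 1.11e-31, and adjusted p = 0.0303 with an estimated correlation). The 5 that rose were Col15a1 (5.80 ± 0.45), Lama2 (2.07), Plod1 (1.36), Col6a3 (1.13) and P4ha2 (0.52), of which P4ha2 turned to -0.16 with library totals. Col15a1 and Lama2 code for basement membrane proteins. Fbln1 (-0.38) and Fbn2 (0.25) were not called. Fibroblast markers fell in 16 of 21 cases, at a median of -3.66 (limma camera adjusted p = 8.61e-12, and adjusted p = 0.0303 with an estimated correlation). The calcium-binding protein S100a4 held 32.0 ± 7.90 against 3429 ± 408 CPM and the filament protein vimentin (Vim) 160.0 ± 34.97 against 3822 ± 247 CPM. Pi16 (12.7 ± 6.12 against 0.440 ± 0.4003 CPM) and Mgp (1.03) rose, and Cd34 (0.47), Dpt (0.02) and Ly6a (-0.72) were not called. Myofibroblast and smooth muscle genes fell in 22 of 28 cases, at a median of -3.67 (limma camera adjusted p = 1.74e-09, and adjusted p = 0.0617 with an estimated correlation). The 5 that rose were desmin (Des, 5777 ± 742 against 73.2 ± 10.9 CPM), which cardiomyocytes also use, the pericyte marker Rgs5 (5.09), Smtn (1.79), Cdh2 (0.85) and Cspg4 (0.82). Libraries of both fractions overlapped for Cspg4, whose call was lost without cardiomyocyte library 2 (0.122) or 3 (0.0695) (edgeR quasi-likelihood adjusted p in parentheses), and Mylk (-0.09) was not called.

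Genes of transforming growth factor beta signalling, a pathway that drives matrix production, were lower in 22 of 28 cases, at a median of -2.26 (limma camera adjusted p = 1.09e-09, and adjusted p = 0.0527 with an estimated correlation). Ctgf, which codes for a matrix-associated growth factor, held 280.5 ± 82.7 against 945 ± 76.8 CPM. Ltbp4 (2.87 ± 0.21) and Tgfbr3 (0.77) rose, with overlapping libraries for Tgfbr3. The call of Tgfbr3 was lost without cardiomyocyte library 2 (0.112) or 3 (0.0978) or nonmyocyte library 1 (0.0625) (edgeR quasi-likelihood adjusted p in parentheses). Ltbp1 (-0.61), Smad4 (0.29), Tgfbi (0.86) and Tgfbr1 (0.42) were not called. Epicardial and mesothelial markers were lower in 7 of 10 cases, at a median of -2.71 (limma camera adjusted p = 0.0123, and adjusted p = 0.142 with an estimated correlation). The retinoic acid enzyme gene Aldh1a2 held 0.708 ± 0.598 against 46.1 ± 4.78 CPM and the transcription factor gene Tcf21 2.88 ± 0.790 against 86.0 ± 17.5 CPM. Krt18 (1.60), Msln (0.42) and Wt1 (0.79) were not called.

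Cell division genes were lower in cardiomyocytes in 46 of 51 cases, with a median of -3.50 (limma camera adjusted p = 1.04e-11, and adjusted p = 0.0259 with an estimated correlation). The cyclin gene Ccnd1 held 47.6 ± 19.7 against 551 ± 58.1 CPM and the mitotic motor gene Kif11 0.0863 ± 0.150 against 5.89 ± 1.12 CPM. Cenpa was the one member higher in cardiomyocytes, at 3.13 ± 2.83 against 0.715 ± 0.500 CPM (edgeR quasi-likelihood adjusted p = 0.0449). Its call was lost without cardiomyocyte library 1 (adjusted p = 0.194), nonmyocyte library 2 (0.0850) or nonmyocyte library 3 (0.129), and 45.6% of its exon bases lie in other genes. Cdk2 (-0.44), E2f2 (-1.77), E2f8 (-0.68) and Pcna (-0.54) were not called. Inhibitors of the cell cycle and senescence genes fell in 10 of 16 cases, at a median of -1.99 (limma camera adjusted p = 0.00113, and adjusted p = 0.0527 with an estimated correlation). Cdkn2a, a tumour suppressor gene, held 0.809 ± 0.0298 against 57.4 ± 2.23 CPM and Cdkn1a 88.4 ± 64.6 against 1365 ± 87.0 CPM. Igfbp5 (137.4 ± 24.01 against 1.86 ± 1.19 CPM), Cdkn1c (3.75) and Cdkn1b (0.89) rose, and Ccng1 (0.10), Cdkn2c (-0.50) and Cdkn2d (1.49) were not called. Ribosomal protein genes were lower in 40 of 46 cases, at a median of -1.12 (limma camera adjusted p = 0.000178, and adjusted p = 0.418 with an estimated correlation). Rplp1, part of the ribosomal stalk, held 523 ± 128.2 against 1781 ± 258 CPM. These levels are uncertain, since ribosomal protein genes have many near-identical processed copies.

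Transcription factor genes divided by lineage. Cardiac transcription factors were higher in 19 of 24 cases, at a median of 3.20 (limma camera adjusted p = 5.95e-10, and adjusted p = 0.0527 with an estimated correlation). The ventricular factor Irx4 held 74.2 ± 12.4 against 0.436 ± 0.295 CPM and the muscle methyltransferase Smyd1 800.4 ± 166 against 5.98 ± 0.579 CPM. Tbx20 (-1.62) and Hand1 fell, the latter with 2 counts in cardiomyocytes and a ratio of 39.4 (95% interval 10.5 to 332) toward nonmyocytes. Mef2a (0.63), Tead1 (-0.53) and Zfpm2 (-0.33) were not called. Mesenchymal transcription factors fell in 30 of 36 cases, at a median of -3.32 (limma camera adjusted p = 1.40e-08, and adjusted p = 0.0527 with an estimated correlation). Creb3l1 held 8.81 ± 1.33 against 227 ± 50.7 CPM, while the Notch target Heyl (4.21 ± 0.57) and Meox1 (2.40) rose. Tbx15 (-0.94), Tcf4 (0.55), Wwtr1 (-0.42) and Zeb1 (-0.09) were not called. Yap1, a growth-control cofactor, fell by a small amount (-0.48 ± 0.15, edgeR quasi-likelihood adjusted p = 0.0130). Its call was lost without cardiomyocyte library 3 (adjusted p = 0.0755) or nonmyocyte library 3 (0.0578).

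**Figure D1:**
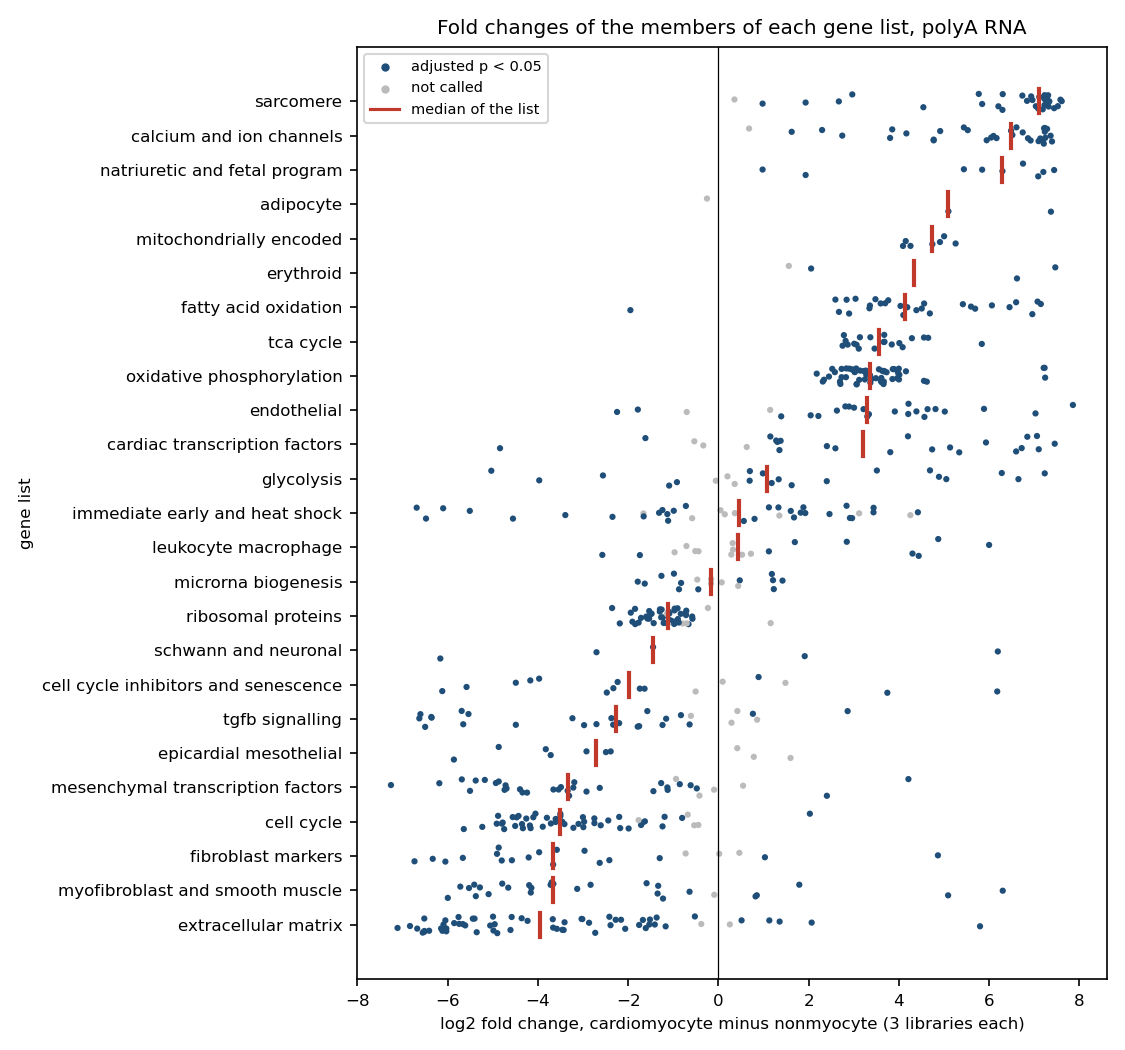
Log2 fold changes, cardiomyocyte minus nonmyocyte, of every tested member of the 25 gene lists in polyadenylated RNA, 1 point per gene, with blue points called at an adjusted p under 0.05, grey points not called and a red bar at the median of each list. Sarcomere genes sit at a median of 7.10 and extracellular matrix genes at -3.95, while the medians of the immediate early and leukocyte lists change sign with library totals.

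Markers of further cell types were measured as well. The cardiomyocyte fraction was parted by gravity and not cultured, and its share of other cells was not tested. Rises of such markers, here and in the other gene and microRNA lists, therefore cannot be assigned to cardiomyocytes themselves. Endothelial genes, markers of vessel lining, rose in the cardiomyocyte fraction in 21 of 25 cases, at a median of 3.30 (limma camera adjusted p = 1.68e-07, and adjusted p = 0.285 with an estimated correlation). The junction protein gene Cdh5 held 279 ± 96.4 against 37.5 ± 5.53 CPM and the lipid carrier gene Fabp4 276 ± 97.4 against 18.4 ± 1.09 CPM. Eng (-1.78) and Plvap (-2.24) fell, and Ednrb (1.15) and Emcn (-0.70) were not called. Of 3 adipocyte genes, Plin4 (762 ± 137.8 against 22.2 ± 1.10 CPM) and Cidea (7.37) rose and Pparg (-0.25) was not called, with a list median of 5.10 (limma camera adjusted p = 0.00185, and adjusted p = 0.0617 with an estimated correlation). Leukocyte and macrophage genes were higher in 7 and lower in 2 of 18 cases (limma camera adjusted p = 0.463). Their median was 0.43, and -0.25 with library totals. The antigen-processing gene Cd74 (33.2 ± 3.02 against 0.478 ± 0.528 CPM) and the complement genes C1qa (4.30), C1qb (4.87) and C1qc (4.44) rose, and the macrophage genes Cd68 (3.18 ± 0.413 against 18.97 ± 4.77 CPM) and Csf1r (-1.74) fell. Of 5 Schwann cell and neuronal genes 2 were higher, among them Dbh (6.19), and 3 were lower (limma camera adjusted p = 0.699). Those that fell were Tubb3 (-6.16), S100b (-2.70) and Mbp (-1.45). The call of Mbp was lost without cardiomyocyte library 2 or 3 (edgeR quasi-likelihood adjusted p = 0.0967 and 0.139) or nonmyocyte library 1 or 3 (0.152 and 0.180).

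Of 4 erythroid genes 3 were higher in cardiomyocytes (limma camera adjusted p = 0.532), namely the globin genes Hba-a1 (129.4 ± 179 against 1.29 ± 0.661 CPM) and Hbb-b2 (95.1 ± 130.0 against 0.512 ± 0.295 CPM) and the receptor gene Epor (2.06). Alas2, at 1.56, was not called. Without nonmyocyte library 1, 2 or 3 the edgeR quasi-likelihood adjusted p was 0.118, 0.103 and 0.126 for Hba-a1 and 0.110, 0.0970 and 0.116 for Hbb-b2. Epor lost its call without cardiomyocyte library 2 (adjusted p = 0.103), cardiomyocyte library 3 (0.0623) or nonmyocyte library 1 (0.0520). Globin copies share sequence, so these levels are uncertain.

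Immediate early and heat shock genes, which can respond to tissue handling, were higher in 16 and lower in 14 of 38 cases (limma camera adjusted p = 0.663). Their median was 0.47 although camera gave a downward direction, and -0.19 with library totals. The immediate early genes Fos (3.44), Atf3 (3.44), Nr4a1 (2.96), Fosb (2.92) and Jun (2.84) rose, and Fosl1 (-6.10) and Fosl2 (-2.35) fell. The small heat shock protein gene Hspb1 held 606 ± 197 against 159 ± 9.91 CPM, while the cytokine gene Ccl2 (13.7 ± 3.86 against 1254 ± 221.2 CPM) and the heme oxygenase gene Hmox1 (44.0 ± 34.8 against 998 ± 58.1 CPM) were lower. Genes of microRNA biogenesis were higher in 5 and lower in 7 of 17 cases, at a median of -0.16 (limma camera adjusted p = 0.862). Those higher were the Argonaute gene Eif2c4 (19.8 ± 2.21 against 7.40 ± 1.52 CPM), Tarbp2 (1.19), Tnrc6b (1.21), Tnrc6c (1.23) and the RNA helicase gene Ddx5. The other Argonaute genes Eif2c1 (-1.26), Eif2c2 (-0.87) and Eif2c3 (-1.63) fell. Dicer1 (0.07), Prkra (-0.47), Rnasen (0.44), Srrt (-0.16) and Tnrc6a (-0.16) were not called. Ddx5 stood at 0.47 ± 0.17 (edgeR quasi-likelihood adjusted p = 0.0270) and turned to -0.21 with library totals. Its call was lost without cardiomyocyte library 2 (adjusted p = 0.0732) or 3 (0.132).

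In all, 20 of 25 gene lists were called by limma camera, 11 up and 9 down, and 4 of them with an estimated correlation as well. Some lists share members, so these are not independent results. Adjusted over the list alone, the counts of most lists were those given above. Exceptions were glycolysis with 15 higher, endothelial genes with 22 higher, leukocyte genes with 6 higher and cell division genes with 47 lower. The others were immediate early genes with 18 higher and 16 lower, cardiac transcription factors with 20 and 3, and mesenchymal transcription factors with 3 and 31.

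The same libraries were used to compare lncRNA genes, most of which carry only a catalogue number in the deposited annotation. Of 2736 lncRNA genes tested, 865 were higher and 527 lower in cardiomyocytes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The most abundant of the higher ones was n265358 on chromosome 11 (108872993 to 108873432) of mm9, 60896 bases from the nearest protein-coding gene Axin2. It held 7956 ± 1102 against 1783 ± 295 CPM (2.16 ± 0.19). Another, on chromosome 16 (35966838 to 35983316), overlaps Parp9 on the opposite strand and held 1861 ± 488 against 380.01 ± 101 CPM. The largest rise at 5 CPM or more in every cardiomyocyte library was that of n286810 on chromosome 10 (80657438 to 80671929), which overlaps the muscle gene Itgb1bp3 on the opposite strand. It had 0 counts in nonmyocytes and was at least 237-fold higher in cardiomyocytes. A gene 405 bases downstream of the muscarinic receptor gene Chrm2, on chromosome 6 (36475015 to 36478418), had 506 counts over the cardiomyocyte libraries and 0 in nonmyocytes.

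Of the lncRNA genes lower in cardiomyocytes, the most abundant was n270541 on chromosome 5 (143664920 to 143665325), 95 bases downstream of the actin gene Actb on the opposite strand. It held 280.4 ± 23.1 against 4104 ± 1237 CPM (-3.87 ± 0.22, edgeR quasi-likelihood adjusted p = 1.55e-08). Next came n413827 on chromosome 10 (61533769 to 61535319), 35084 bases from the nearest coding gene, with 4.996 ± 1.33 against 377.2 ± 12.8 CPM (-6.17 ± 0.19). A gene on chromosome 18 (52688314 to 52736979), overlapping the collagen cross-linking enzyme gene Lox on the opposite strand, had 2 counts in cardiomyocytes and a ratio of 191 (95% interval 52.4 to 1583) toward nonmyocytes. The libraries do not keep the strand, so reads of these lncRNA genes and of coding genes that overlap them cannot be told apart. Without the lncRNA genes that overlap a coding gene or lie within 5 kb of one, 310 remained to be tested, with 100 higher and 86 lower, a count made after the data were seen. With no filter on low counts, 1619 lncRNA genes were higher. The list of widely studied lncRNA names had 13 entries in the table, of which 9 stood at 0 in all libraries and 0 passed the filter for testing.

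MicroRNAs, short RNAs that pair with messenger RNAs, were compared in the small RNA libraries to ask the same question. MicroRNAs of striated muscle rose in cardiomyocytes, while miR-21-5p, the called arms of miR-34b and miR-34c and a large imprinted cluster on chromosome 12 fell. With an estimated correlation the lists of muscle microRNAs and of that cluster were not called (limma camera adjusted p = 0.397 and 0.303). The muscle microRNA miR-486-5p on chromosome 8 (24253059 to 24253080) held 247937 ± 138708 against 1613 ± 2049 CPM (7.27 ± 1.03, edgeR quasi-likelihood adjusted p = 0.00371). Its log2 fold change ran from 6.77 to 9.60 over the left-out libraries, the highest without nonmyocyte library 3. Reads opposite the 3p arm of its precursor stood at a like level, 315654 CPM in cardiomyocytes. Whether both count the same microRNA was not tested, so the level of miR-486-5p is uncertain. For miR-21-5p, abundant in fibroblasts, on chromosome 11 (86397622 to 86397643), the values were 1256 ± 674 against 41707 ± 8582 CPM (-5.05 ± 0.54, edgeR quasi-likelihood adjusted p = 0.000802). Of 343 microRNA arms tested, 65 were higher and 116 lower in cardiomyocytes and 162 were not called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The count of higher ones was 36 without cardiomyocyte library 2 and 29 without nonmyocyte library 2. Library totals alone moved the median log2 fold change by -1.64, with 28 higher and 187 lower. The share of higher calls was then 13.02%, against 35.9% with the scaling used here. The shift was -0.10 with the size factors of DESeq2 and -0.34 with upper quartiles.

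Among other abundant microRNAs higher in cardiomyocytes, miR-181a-2-5p held 37112 ± 7650.0 against 7203 ± 2102 CPM and the muscle microRNA miR-133a-2-3p 234255 ± 65577 against 3356 ± 5564 CPM. The call of miR-133a-2-3p (edgeR quasi-likelihood adjusted p = 0.0288) was lost without cardiomyocyte library 2 (0.0729), cardiomyocyte library 3 (0.0550) or nonmyocyte library 2 (0.0683). Its near-identical copy miR-133a-1-3p held 65989.6 ± 19898 against 1736 ± 2905 CPM (edgeR quasi-likelihood adjusted p = 0.0461). Without cardiomyocyte library 1, 2 or 3 or nonmyocyte library 2 its adjusted p was 0.0567, 0.106, 0.0858 and 0.106. Without nonmyocyte library 3 the log2 fold changes of these copies went from 6.13 to 10.98 and from 5.26 to 10.45. Reads can be split between such copies, so both levels are uncertain. miR-148a-3p held 25893 ± 15476 against 6512 ± 801 CPM and was not called without nonmyocyte library 2 (adjusted p = 0.110). miR-30d-5p, at 22664 ± 8272 against 7137 ± 1144 CPM, was not called without cardiomyocyte library 2 (0.0697) or nonmyocyte library 2 (0.136). The largest folds at 100 CPM or more in every cardiomyocyte library belonged to miR-133a-2-5p, with 0 counts in nonmyocytes and at least 710-fold higher, to miR-133a-1-5p, with 1 count and a ratio of summed counts of 1111 (95% interval 199.2 to 43920), and to miR-490-3p (8.25 ± 1.39, and 11.11 without nonmyocyte library 3). The bound of miR-133a-2-5p sums counts, so it leans on the deepest cardiomyocyte library, number 3, with 831 CPM against 245 and 417 in libraries 1 and 2. The 1 count of miR-133a-1-5p lies in the shallow nonmyocyte library 3, so its means, 257 ± 159 against 2.26 ± 3.92 CPM, give a ratio below its interval.

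Sequences on the strand opposite to the annotated precursor took 39.3%, 28.9% and 18.5% of the cardiomyocyte counts and 5.57%, 5.96% and 9.92% of the nonmyocyte counts. The highest of them, opposite the 3p arm of the miR-486 precursor, held 315654 ± 158788 against 2169 ± 2948 CPM. The next, on chromosome 18 (61557491 to 61557512), held 157999 ± 12472 against 1784 ± 2088 CPM. In nonmyocyte library 3 they stood at 5572 and 4194 CPM, above libraries 1 and 2. Without that library their log2 fold changes were 9.82 and 8.43, and the lowest over the left-out libraries were 6.66 and 6.02. Opposite-strand sequences entered no microRNA list or host pair, and which mature microRNAs they are was not established. The one opposite the 3p arm of miR-486 ran beside miR-486-5p over nonmyocyte libraries 1 to 3 (389, 547 and 5572 against 353, 509 and 3977 CPM). It may thus not be a separate microRNA, which was not tested. Without all opposite-strand sequences 64 microRNA arms were higher, a choice made after the data were seen.

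On the nonmyocyte side, miR-127-3p held 685 ± 135 against 18613 ± 4917 CPM, miR-541-5p 46.3 ± 26.01 against 7377 ± 2237 CPM and miR-434-3p 54.8 ± 11.7 against 6063 ± 1355 CPM, all 3 from the imprinted cluster. miR-125b-1-3p held 71.1 ± 46.8 against 4456 ± 1961 CPM. Calls of 3 other abundant ones did not hold when a library was left out, which also lowers the power of the test. Over the 6 left-out libraries their log2 fold changes ran from -2.16 to -0.97 for let-7i-5p, -1.40 to -0.59 for miR-10b-5p and -1.72 to -0.88 for miR-125a-5p. let-7i-5p (4409 ± 2245 against 14581 ± 1683 CPM) lost its call without cardiomyocyte library 2 or 3 (edgeR quasi-likelihood adjusted p = 0.0838 and 0.0635) or nonmyocyte library 1, 2 or 3 (0.271, 0.0754 and 0.0563). miR-10b-5p (3388 ± 734 against 8551 ± 1984 CPM) lost it without cardiomyocyte library 2 (0.107) or nonmyocyte library 1, 2 or 3 (0.430, 0.112 and 0.0654). miR-125a-5p (3435 ± 1450.3 against 9276 ± 2589 CPM) lost it without any 1 of the 6 libraries, namely cardiomyocyte library 1 (0.0541), 2 (0.0608) or 3 (0.112) or nonmyocyte library 1 (0.220), 2 (0.103) or 3 (0.181). The steepest falls at 100 CPM or more in every nonmyocyte library were those of miR-34b-3p, with 1 count in cardiomyocytes and a ratio of 1752 (95% interval 314 to 69260), and of miR-667-3p, with 2 counts and a ratio of 533 (95% interval 147 to 4408). miR-34c-5p (-8.09 ± 0.60), miR-183-5p (-8.07 ± 0.93) and miR-431-5p (-7.95 ± 0.56) followed. Over the left-out libraries these ran from -8.34 to -7.15, from -9.33 to -7.26 and from -8.18 to -7.38.

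**Figure D2:**
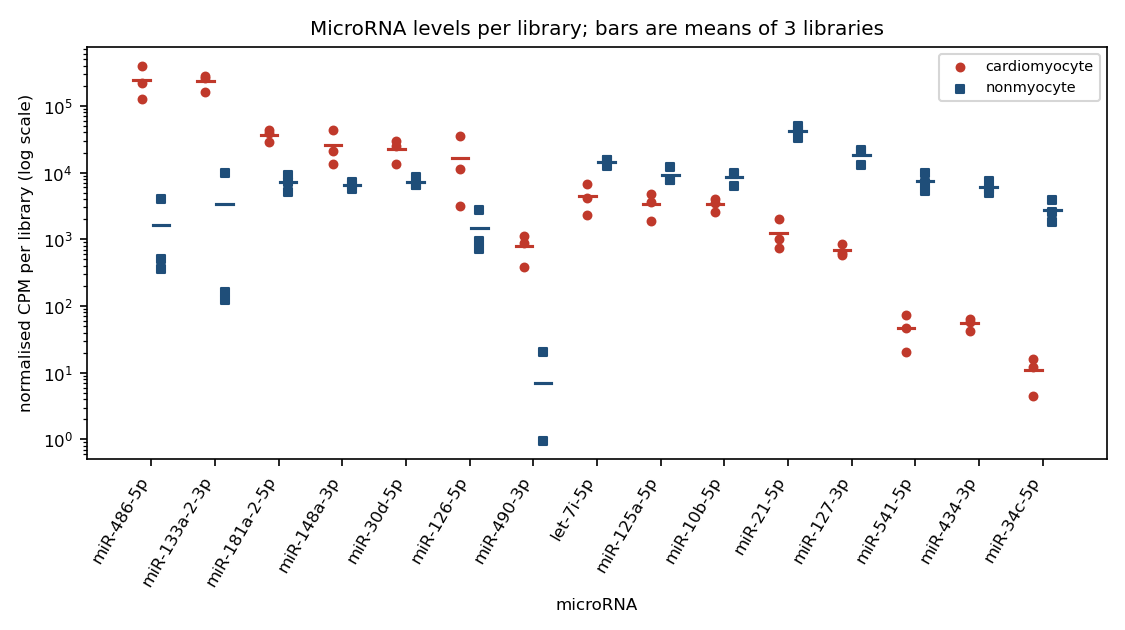
Normalised CPM on a log axis of 15 microRNAs named in the text, with red circles for the 3 cardiomyocyte and blue squares for the 3 nonmyocyte libraries and bars at the means; values of 0 are not drawn on the log axis. Nonmyocyte library 3 lies at 3977 CPM for miR-486-5p, above the 353 and 509 CPM of the other two.

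Muscle microRNAs rose in 12 of 15 cases, at a median of 6.13 (limma camera adjusted p = 6.17e-08, and adjusted p = 0.397 with an estimated correlation). Among them were miR-499-5p (5.59), miR-149-5p (5.45) and miR-208b-3p, which had 1 count in nonmyocytes and a ratio of summed counts of 1795 (95% interval 321.9 to 70910). That count too lies in nonmyocyte library 3, and the means, 353 ± 385 against 2.26 ± 3.92 CPM, give a ratio below the interval. Without library 3 miR-499-5p stood at 8.82 and miR-149-5p at 6.72. The call of miR-499-5p was lost without cardiomyocyte library 2 (0.0842) or 3 (0.0901) or nonmyocyte library 2 (0.123) (edgeR quasi-likelihood adjusted p in parentheses). miR-1a-1-3p (4.70), miR-133b-3p (4.65) and miR-208a-3p (3.78) were not called, but their nonmyocyte counts lie mostly in library 3, at 244, 74.7 and 47.5 CPM there. Without that library their log2 fold changes were 9.54, 9.51 and 7.03, and all 3 were called. In nonmyocyte library 3 miR-133a-2-3p stood at 9780.2 CPM, against 122.3 and 165 CPM in libraries 1 and 2. Without library 3, 93 microRNA arms were higher and 111 lower. The miR-30 family rose in 8 of 12 cases, at a median of 2.42 (limma camera adjusted p = 0.000459, and adjusted p = 0.397 with an estimated correlation), led by miR-30c-1-3p (344.7 ± 27.3 against 16.8 ± 11.3 CPM). The log2 fold change of miR-30c-1-3p ran from 3.99 to 5.48 over the left-out libraries. miR-30c-2-5p lost its call without cardiomyocyte library 2 (0.0610) or nonmyocyte library 2 (0.0946) (edgeR quasi-likelihood adjusted p in parentheses). miR-30a-5p (0.74), miR-30b-5p (1.38), miR-30d-3p (2.23) and miR-30e-5p (2.56) were not called, but all except miR-30a-5p were without nonmyocyte library 3.

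Of the microRNAs listed for the imprinted Dlk1-Dio3 cluster 46 of 48 fell, at a median of -6.01 (limma camera adjusted p = 1.74e-17, and adjusted p = 0.303 with an estimated correlation). With the 4 members that were at 0 in a group set to the bound of 3 counts, the median was -5.72. The 2 that rose are the arms of miR-345, which lies 615801 bases from Dlk1 and outside the cluster, and all 46 tested members between Dlk1 and Dio3 fell. The arms of miR-345 stood at 1.59 for the 3p arm, which turned to -0.057 with library totals, and 1.94 for the 5p arm. The call of miR-345-5p was lost without cardiomyocyte library 2 (0.0697) or 3 (0.0536) or nonmyocyte library 2 (0.136) (edgeR quasi-likelihood adjusted p in parentheses), and that of miR-345-3p without cardiomyocyte library 2 (0.0642) or 3 (0.0585) or nonmyocyte library 2 (0.137). Fibroblast and mesenchymal microRNAs fell in 26 and rose in 4 of 56 cases, at a median of -1.46 (limma camera adjusted p = 0.0190, and adjusted p = 0.468 with an estimated correlation). The list was not called without cardiomyocyte library 1 (adjusted p = 0.244) or nonmyocyte library 3 (0.0522). Those that rose were miR-322-5p (3.13), miR-322-3p (1.64, and -0.014 with library totals), miR-335-3p (4.11) and miR-542-5p. Over the left-out libraries the log2 fold change ran from 1.985 to 3.894 for miR-322-5p and from 3.776 to 4.812 for miR-335-3p. The call of miR-322-5p was lost without cardiomyocyte library 2 (0.0610) or 3 (0.0901) or nonmyocyte library 2 (0.120) (edgeR quasi-likelihood adjusted p in parentheses), and that of miR-322-3p without cardiomyocyte library 2 (0.0817) or 3 (0.0732) or nonmyocyte library 2 (0.159). miR-542-5p had 2 counts in nonmyocytes, a ratio of summed counts of 48.0 (95% interval 13.1 to 399.6) and overlapping libraries. Its means, 20.5 ± 17.9 against 2.43 ± 3.78 CPM, give a ratio below the interval, since 1 of the counts lies in the shallow library 3, and its call was lost without nonmyocyte library 2 (adjusted p = 0.164). miR-34c-3p had 0 counts in cardiomyocytes and was at least 180-fold lower there.

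The remaining 7 microRNA lists tested were not called by limma camera. In the let-7 family let-7a-2-5p (1.25), let-7g-5p (1.49) and let-7f-2-3p (3.49) rose and let-7i-5p fell among 18 arms (limma camera adjusted p = 0.175). With library totals let-7a-2-5p turned to -0.38 and let-7g-5p to -0.18, and let-7f-2-3p was not called without nonmyocyte library 2 (adjusted p = 0.0550). Calls were lost for let-7a-2-5p without cardiomyocyte library 2 (0.0729) or nonmyocyte library 2 (0.119) and for let-7g-5p without cardiomyocyte library 2 (0.0948) or 3 (0.107) or nonmyocyte library 2 (0.201). In the miR-17-92 cluster and its paralogs miR-25-5p (-2.24) and miR-92b-3p (-2.94) fell among 14 arms. Its median was -0.16 although camera gave an upward direction (adjusted p = 0.787). miR-25-5p lost its call without cardiomyocyte library 2 (0.0773) or 3 (0.0536) or nonmyocyte library 1 (0.169), 2 (0.0795) or 3 (0.0563), and miR-92b-3p without cardiomyocyte library 2 or nonmyocyte library 1 or 2 (edgeR quasi-likelihood adjusted p = 0.0875, 0.116 and 0.0580). In the miR-29 family 0 of 5 arms and in the miR-23, miR-27 and miR-24 clusters 0 of 8 were called by edgeR (limma camera adjusted p = 0.448 and 0.528). At an unadjusted p under 0.05 there were 1 and 0, with DESeq2 1 and 0, and with limma voom 1 and 1. Without nonmyocyte library 3 miR-29c-3p was called (log2 fold change 4.15, edgeR quasi-likelihood adjusted p = 0.00345). Medians of the let-7, miR-29 and miR-23 lists were 0.49, 1.26 and 0.31, and -1.14, -0.42 and -1.37 with library totals. The miR-23 list was at -0.023 with upper quartiles.

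Blood cell microRNAs had 3 higher, miR-142-5p (2.91), miR-150-5p (1125 ± 425 against 60.8 ± 76.7 CPM) and miR-223-3p (3.92), and 2 lower, miR-146-5p (-3.92) and miR-146b-5p (-5.15), of 10 (limma camera adjusted p = 0.260). Their median was 0.82, and -0.82 with library totals. Without nonmyocyte library 3 the rises were larger, at 3.67 for miR-142-5p, 6.38 for miR-150-5p (4.37 with all libraries) and 4.63 for miR-223-3p. Both falls were smaller without nonmyocyte library 3, at -2.06 and -3.75, and lost their call without cardiomyocyte library 2 (edgeR quasi-likelihood adjusted p = 0.0855 and 0.0551), and without nonmyocyte library 2 so did miR-142-5p (0.0683) and miR-223-3p (0.0914). Of 3 epithelial microRNAs, miR-182-5p (-6.29) and miR-183-5p fell and miR-203-3p (3.54) rose (limma camera adjusted p = 0.297). Without nonmyocyte library 3 miR-203-3p stood at 5.18, and it lost its call without cardiomyocyte library 2 or 3 or nonmyocyte library 1 or 2 (edgeR quasi-likelihood adjusted p = 0.0929, 0.0833, 0.0607 and 0.154). Neuronal microRNAs had 4 higher, from miR-128 and miR-9, 4 lower, from miR-129 and miR-375, and miR-138-2-5p not called (limma camera adjusted p = 0.787). Of these, miR-128-1-3p (2.85) lost its call without nonmyocyte library 2 (adjusted p = 0.0579), and miR-128-2-3p (2.43) without cardiomyocyte library 2 (0.0729) or nonmyocyte library 2 (0.137). miR-9-2-5p (2.18) lost it without cardiomyocyte library 2 (0.0605) or nonmyocyte library 1 (0.0696) or 2 (0.201), and miR-375-3p (-2.29) without nonmyocyte library 2 (0.0775). Both arms of the endothelial miR-126 rose, too few for a list test. miR-126-5p held 16503 ± 16447 against 1475 ± 1121 CPM and lost its call without cardiomyocyte library 2 or 3 or nonmyocyte library 2 (adjusted p = 0.0521, 0.0545 and 0.0973), and miR-126-3p (3.71) without nonmyocyte library 2 (0.0777). Their log2 fold changes ran from 2.44 to 4.48 and from 2.78 to 5.08 over the left-out libraries, both highest without nonmyocyte library 3. Adjusted over the list alone, muscle microRNAs had 14 higher, and in the let-7 family 1 was higher, with let-7i-5p not called. The 2 falls of the miR-17-92 cluster were not called then, and the other microRNA lists had the counts given above.

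Many microRNAs are transcribed within a protein-coding host gene, which allowed both assays to be set side by side. Of 15 host genes called together with their microRNAs, 14 changed in the direction of the microRNA (93.3%, one-sided permutation p = 0.00224 over 100000 reassignments of the hosts). The cardiac myosin gene Myh6 stood at 7.19 and miR-208a at 10.82, and Myh7 at 7.44 and miR-208b at 9.48. Chrm2 (7.07) with miR-490 (8.25) and Myh7b (7.15) with miR-499 (5.59) followed. The value of miR-208a is that of its 5p arm, which had 0 counts in nonmyocytes, so it is a fitted value and no bound, as is that of miR-208b-3p with 1 count. Its 3p arm was not called (edgeR quasi-likelihood adjusted p = 0.138). Downward pairs included Slit3 with miR-218 (-4.45 and -5.37) and Lpp with miR-28 (-2.93 and -1.89). MicroRNAs were matched to hosts by number, and whether each copy lies within its host was not checked. The miR-218 value is the median of miR-218-1-3p (-7.17) and miR-218-2-5p (-3.58), which come from different copies. Copies of miR-30c were likewise joined for the host Nfyc. The pair with opposite signs was the focal adhesion kinase gene Ptk2 (-2.55) and miR-151 (2.06). Among all 27 pairs tested, whatever their p, 22 had the same sign. Without nonmyocyte small RNA library 2 only 7 pairs were left, with the same sign in 100% of them, and the permutation test no longer passed its threshold.

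**Figure D3:**
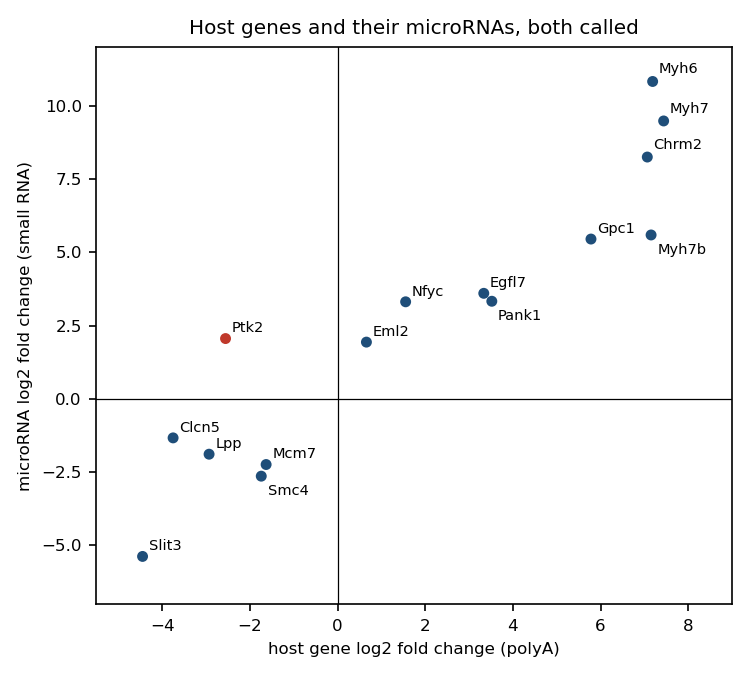
Log2 fold change, cardiomyocyte minus nonmyocyte, of 15 host genes in polyadenylated RNA (horizontal axis) against the median log2 fold change of the called arms of their microRNAs in small RNA (vertical axis), 1 point per pair, with the pair of opposite signs in red. Of the 15 pairs 14 lie in the quadrants where both signs are the same.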

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

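The counts without lncRNA genes near coding genes and without opposite-strand small RNAs, and the values of genes named outside the rule, were chosen after the data were seen. Of the values recomputed for single named genes and microRNAs, 93.8% in polyadenylated RNA and 83.4% in small RNA kept their direction and side of the threshold. Another 2.29% and 10.7% lost their call, 2.71% and 3.16% gained one and 1.18% and 2.77% changed sign. Small RNA had 83170 counts in the shallowest library and a biological coefficient of variation of 0.639 against 0.251 in polyadenylated RNA, and the effects of depth and spread were not separated. Testing against a 2-fold change, a stricter question, left 3023 genes higher and 2996 lower in polyadenylated RNA. With library totals alone, which takes the shift of the median as real, 7106 genes were lower, 5875 by at least 2-fold, and microRNA calls became 28 higher and 187 lower. With no filter, which tests more genes, 1619 lncRNA genes were higher. Away from coding genes, where fewer are tested, 100 were higher and 86 lower. An estimated correlation, which also lowers power, left 4 gene lists and 0 microRNA lists. The test fry, which asks whether a list moves on balance one way, called 23 and 6. Leaving out 1 library gave 29 to 95 microRNAs higher and at least 78 lower, 4211 to 5367 genes higher, 4286 to 5195 lower, 783 to 1013 lncRNA genes higher and 471 to 783 lower. Gene lists called stayed at 20, microRNA lists at 3 to 4, and the host share at 90.9% to 100%. Testing the lincRNA class alone gave no value, since 18 of its 21 genes stood at 0 and 0 were tested.

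The log2 fold changes that follow changed sign, and the cause was not tested. With library totals they were -0.58 for Ccng1, -0.24 for Cd34, -0.21 for Ddx5, -0.61 for Dicer1, -0.69 for Dpt, -0.47 for Fbn2, -0.016 for Gjc1 and -0.32 for Ldha. Totals also gave -0.065 for Mef2a, -0.20 for Msln, -0.33 for Neb, -0.16 for P4ha2, -0.49 for Pgk1, -0.24 for Rnasen, -0.39 for Smad4, -0.14 for Tcf4 and -0.26 for Tgfbr1. Among microRNAs these were -0.38 for let-7a-2-5p, -0.95 for let-7f-2-5p, -0.18 for let-7g-5p, -1.57 for miR-10a-5p, -1.03 for miR-16-1-5p, -1.07 for miR-16-2-5p and -0.81 for miR-20a-5p. The others with totals were -0.64 for miR-23b-3p, -1.56 for miR-25-3p, -0.59 for miR-27a-3p, -0.94 for miR-27b-3p, -1.04 for miR-29a-3p, -0.95 for miR-30a-5p, -0.32 for miR-30b-5p, -0.014 for miR-322-3p, -0.057 for miR-345-3p and -1.28 for miR-92-1-3p, of which miR-10a-5p, miR-25-3p and miR-92-1-3p were then called lower, as were Ccng1, Dicer1, Ldha and Smad4. With DESeq2's size factors the values were -0.027 for Dpt and -0.049 for miR-10a-5p, and with upper quartiles -0.018 for Dicer1, -0.093 for Dpt, -0.38 for miR-10a-5p and -0.11 for miR-25-3p. DESeq2 gave -0.027 for Dpt and -0.049 for miR-10a-5p, and voom -0.12 for Msln, -0.0098 for miR-10a-5p and -0.0019 for miR-16-2-5p. Without the filter they were 0.013 for Pkm2, -0.068 for miR-10a-5p and -0.16 for miR-25-3p, and without the 3 most abundant microRNAs -0.0051 for miR-25-3p. Leaving out 1 library gave -0.11 to 0.26 for Ccng1, -0.32 to 0.26 for Dpt, -1.01 to 0.0096 for E2f8, -0.37 to 0.65 for Fbn2, -0.35 to 0.84 for Msln and -0.27 to 0.20 for Mylk. Further ranges were -0.12 to 0.64 for Neb, -0.13 to 0.053 for Pkm2, -0.55 to 0.026 for Pparg, -0.19 to 0.091 for Tnrc6a, -0.23 to 0.043 for Zeb1 and -0.61 to 0.14 for let-7c-1-5p. The remaining ones were -0.36 to 0.94 for miR-10a-5p, -0.11 to 1.31 for miR-16-1-5p, -0.15 to 1.39 for miR-16-2-5p, -0.065 to 1.53 for miR-20a-5p, -0.26 to 0.78 for miR-25-3p, -1.99 to 0.25 for miR-29a-5p, -0.051 to 1.28 for miR-30a-5p and -0.66 to 0.14 for miR-93-5p. The miR-17-92 list changed direction with fry (adjusted p = 0.0777) and without cardiomyocyte library 1 (limma camera 0.939), and the neuronal list without cardiomyocyte library 2 or 3 (0.974 and 0.894). Their adjusted p ranged over the left-out libraries from 0.729 to 0.970 and from 0.704 to 0.974.

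Whether the replicate number pairs the fractions stayed open. Deviations from the group means of libraries with the same number correlated at 0.245, 0.0511 and 0.194 over 10138 genes and at 0.0419, -0.0992 and 0.246 over 340 microRNA arms. Libraries of unlike number correlated at -0.279 to 0.124 in polyadenylated RNA and at -0.408 to 0.374 in small RNA. In polyadenylated RNA cardiomyocyte libraries 1 and 3 correlated best with the nonmyocyte library of their number. Cardiomyocyte library 2 correlated better with nonmyocyte library 3 (0.0835) than with library 2. With the replicate number as a block, 4656 genes were higher and 4843 lower, 3777 and 3858 of them by at least 2-fold, with 830 lncRNA genes higher. There were 59 and 99 microRNAs, 20 gene lists, 4 microRNA lists and a host share of 92.3%, and the sign changed to -0.042 for Dpt, -0.032 for Fbn2 and -0.0066 for miR-10a-5p. Of the named microRNAs 11 then lost their call (edgeR quasi-likelihood adjusted p in parentheses), namely let-7a-2-5p (0.0652), let-7g-5p (0.0731), miR-10b-5p (0.0691), miR-125a-5p (0.0509), miR-148a-3p (0.0618), miR-30d-5p (0.0617), miR-322-3p (0.0952), miR-345-3p (0.0973), miR-345-5p (0.0509), miR-375-3p (0.0861) and miR-542-5p (0.0604). Another 5 gained one, namely miR-133b-3p (0.00671), miR-1a-1-3p (0.00291), miR-208a-3p (0.0115), miR-29c-3p (0.0138) and miR-30e-5p (0.0134). In polyadenylated RNA Mbp lost its call (0.0939) and 10 named genes gained one.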

Other observations

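The comparisons of related genes and of microRNA arms, and the tests of the muscle microRNAs, of the sarcomere transcripts and of the sample splits, were chosen after the results were seen, while both tests of lncRNA genes and their neighbours were set before. Several genes with a muscle form and a general form moved apart, while others rose together, such as the hexokinases Hk2 (3.51) and Hk1 (0.99) and the cytochrome oxidase subunits Cox7a1 (7.21) and Cox7a2 (2.44). The muscle enolase Eno3 rose (log2 fold change 6.28 ± 0.18 SE) while Eno1 fell (-2.56 ± 0.17), and the phosphoglycerate mutase Pgam2 rose (6.65 ± 0.18) while Pgam1 fell (-1.09 ± 0.28). Levels of Eno1 and Pgam1 were low and are uncertain, as said above. Of other cytochrome oxidase pairs, Cox6a2 (7.24) rose and Cox6a1 (-0.97) fell, while Cox8b (7.23) rose and Cox8a (-0.26) was not called. Glucose carriers followed, with Slc2a4 at 7.23 and Slc2a1 at -0.92, and so did the carnitine acyltransferases Cpt1b (6.06) and Cpt1a (-1.95). Lactate dehydrogenase B (Ldhb), the heart form, rose by 5.05 on the log2 scale, whereas Ldha, with 800.3 ± 112 against 623 ± 16.8 CPM, was not called (edgeR quasi-likelihood adjusted p = 0.0648).

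The balance between the 5p and 3p arms of a microRNA precursor differed between fractions for 9 of 90 precursors with both arms tested (limma, Benjamini-Hochberg adjusted p under 0.05; 20 at an unadjusted p under 0.05). In 5 of the 9 an arm was under 1 CPM in a group, so the size of their ratio depends on the offset added before taking logs. For miR-125b-1 the log2 ratio of 5p to 3p was 4.72 in cardiomyocytes and -1.14 in nonmyocytes (difference 5.86 ± 0.93 SE, limma adjusted p = 0.0121). Its 3p arm fell and its 5p arm was not called. For miR-181a-1 the ratios were 7.25 and 3.67 (difference 3.58 ± 0.49), and for miR-181c 4.52 and 1.52 (difference 2.99 ± 0.49). The 5p arms of miR-125b-1 and miR-181a-1 have near-identical copies, so their levels are uncertain. No explanation of these differences was tested.

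Muscle microRNAs and other sequences abundant in cardiomyocytes stood in nonmyocyte small RNA library 3 at a median of 3.58% of the cardiomyocyte level, against 0.161% in libraries 1 and 2, over the 8 sequences at 1000 CPM or more in cardiomyocytes and under 1% of that in libraries 1 and 2. Random sampling at low depth is argued against for these sequences as a set. Libraries 1 and 2 thinned to the depth of library 3 reached at most 4280 CPM summed over these sequences in 1000 draws, against 51340 CPM measured, both on library totals without TMM scaling. These sequences were picked as low in libraries 1 and 2, which lowers the draws, but their level in library 3 was no part of that rule. Effects of low depth other than random sampling were not tested. RNA of cardiomyocytes in that library stays open. Of the 8 sequences 87.5% lay within 3-fold of the median share, as a common source needs. Yet the shares ran from 1.60% for miR-486-5p to 12.65% for miR-1a-1-3p. The 8 sequences were also picked after the pattern was seen and come from only 4 precursor families. Whether cardiomyocytes were in the culture of that number is open too, since the sarcomere sum of nonmyocyte polyadenylated RNA library 3 was 0.911 times that of libraries 1 and 2, but the numbers are not known to mark a culture. Other biological differences of that culture were not tested.

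Transcripts of the sarcomere were present in all nonmyocyte libraries, at a median of 0.782%, 0.683% and 0.595% of the cardiomyocyte level in libraries 1 to 3. Reads crossing over in equal number from the cardiomyocyte libraries are argued against, since library 2, the shallower one, then needs 1.33 times the share of library 1 and had 0.873 times, with 25 of 26 members lower. RNA of cardiomyocytes in the nonmyocyte libraries is a candidate explanation, as 0% of the 180 genes at 1000 CPM or more in cardiomyocytes lay below 0.5 of the median sarcomere share, so their shares look like a common floor. Transcription of sarcomere genes in the cultured cells themselves cannot be told apart from it, with 73.1% (19 of 26) of the members within 1.5-fold of their median share, between the bounds set for either reading. If such a floor exists, folds of genes specific to cardiomyocytes may be understated, whether abundant or scarce, since such RNA would bring each transcript at a like share.

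lncRNA genes often changed in the direction of the nearest tested coding gene. Of those called together with it, 864 of 930 (92.9%) did so within 5 kb and 45 of 71 (63.4%) over 50 kb, a difference of 29.5 percentage points (Fisher's exact test p = 2.46e-11; gene pairs are not independent). Reads of the coding gene counted on the lncRNA may contribute to this. Transcription past the 3' end may as well, since lncRNA genes downstream on the same strand shared the sign in 95.6% of cases and those upstream on the opposite strand in 85.5%, 10.2 percentage points apart (Fisher's exact test p = 0.0269). Shared regulation of neighbouring genes was not tested and stays open beside both.

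The 6 libraries of an assay allow 10 splits into 3 against 3, too few for a share under 0.05. Each other split puts libraries of both fractions in each group, so the difference between fractions adds to the spread within groups. Few or no single genes can then be called, and a highest other value of 0 says nothing about chance. In 1 of the 10 splits, the real one, as many genes were called for polyadenylated RNA (9389, highest other 0), at 2-fold or more (7721, highest other 0), for lncRNA genes (1392, highest other 0), for microRNA arms (181, highest other 0) and for gene lists (20, highest other 19). For microRNA lists 6 of the 10 splits gave as many as the real one (4, highest other 5). List p-values with the preset correlation compare genes with genes, so lists could be called in splits where no single gene was. Small list p-values are therefore no measure of agreement between libraries.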
